A study of Mus musculus with 2 samples.

How the data were processed

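Neural tube tissue of mouse embryos at 15.5 days was profiled by microRNA sequencing in 2 libraries, labelled as biological replicates, from pools of 78 and 62 embryos of strain B6NCrl with both sexes mixed. The deposited tables hold raw read counts per annotated miRNA gene, 1 table per library, as whole numbers that sum to different totals. Per the README texts deposited with the samples, the tables are gene quantifications on genome build mm10 with annotation release GENCODE M4. The aligner, the counting tool, adapter trimming and their versions are not given in the sources used here. Each deposited table gives counts without regard to strand, on 1 strand and on the other, and the unstranded value equals the sum of both in every gene, with 0 exceptions. The column with the larger total was taken as the sense strand, as fixed before the data were examined, and holds the counts used throughout.

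The 4 leading entries of each table name no gene. They hold 45.7% of the 7925935 reads of library 1 and 47.7% of the 11738914 reads of library 2, and were left out of library sizes and tests. Unmapped reads made up 14.3% and 15.9%, multimapping reads 29.4% and 29.7%, and reads outside any annotated miRNA gene 1.96% and 2.14%, with 0 ambiguous reads in both. Multimapping reads were therefore not counted in any gene, which lowers the count of a miRNA gene whose sequence occurs at more than 1 place. Sense counts came to 4228685 in library 1 and 6039889 in library 2, a ratio of 1.43 of library 2 to library 1. At least 1 count was found for 631 and 651 genes, and at least 10 counts for 375 and 389. For PCR-amplified reads without molecular identifiers, intervals and detection limits cover counting error only. A limit of detection was set at 3 counts.

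Gene symbols and positions came from GENCODE M21, on the same assembly as mm10. Of 1973 gene identifiers, 1894 matched without the version number, all of them annotated as miRNA, and 1815 also matched with it. Coordinates are printed only for genes whose version matched, and host genes are those on the same strand in M21. The 79 unmatched identifiers held 2 counts in library 1 and 4 counts in library 2. M21 holds 2202 miRNA genes, of which 308 were not analysed here. A gene was marked as having a near-identical copy when its precursor shared a stretch of 20 bases with another annotated miRNA precursor.

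CPM was computed from the sense-strand counts in miRNA genes, with their sum as the library size. Detection required at least 10 counts in each library. Library sizes were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3). The median log2 ratio of library 1 to library 2 was -0.0023 with TMM and 0.032 with library sizes alone. Each detected gene was compared between the libraries with an exact binomial test, two-sided, against the share given by the TMM effective sizes, with Benjamini-Hochberg adjustment at 0.05. Ratios carry 95% exact (Clopper-Pearson) counting intervals and shares 95% Wilson intervals. The biological coefficient of variation was the square root of edgeR's common dispersion with an intercept-only design. DESeq2 1.42.0 size factors, library sizes alone, no filter, stricter and looser filters, other pseudocounts, unstranded counts, thinning of the deeper library and leaving out either library were run as alternatives. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9. No test between groups, no outlier test, no pairing and no other split of the samples was possible with 1 group of 2.

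The binomial comparison was tested on simulated counts for the 363 detected genes at the real depths, with 200 of them changed. It recovered 80.6% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold, and called 4.29% of unchanged genes. The simulated counts varied by sampling only. For simulated coefficients of variation of 0.1 and 0.3 in 363 genes, edgeR's estimate was 0.0997 and 0.296. All genes of a simulation had the same coefficient, whereas in the data it was 34.3%, and 14.8% with 23 genes left out. The simulation therefore does not test how well a single shared value describes these genes.

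The 22 gene lists were fixed before the data were examined and are defined by gene symbol stems. They are neuron-enriched (Mir124, Mir128, Mir129, Mir132, Mir137, Mir138, Mir153, Mir212, Mir218, Mir7), Mir9 with Mir92b, glia (Mir219, Mir338), let-7 (with Mir98), Mir125 with Mir99 and Mir100, Mir181, Mir30, Hox clusters (Mir10, Mir196, Mir615), the Mir17 cluster and paralogs, the Dlk1-Dio3 region, the Sfmbt2 cluster (Mir297, Mir466, Mir467, Mir669), erythroid (Mir451a, Mir144, Mir486), leukocyte (Mir142, Mir223, Mir150, Mir155), striated muscle (Mir1, Mir133, Mir206, Mir208, Mir499), liver (Mir122), epithelial (the Mir200 family with Mir141 and Mir429, Mir203, Mir205), endocrine, pancreas and gut (Mir375, Mir192, Mir194, Mir215, Mir216, Mir217), the Mir183 cluster, endothelial (Mir126a), mesenchyme and smooth muscle (Mir143, Mir145, Mir199, Mir214, Mir140), pluripotency (Mir290 to Mir295, Mir302, Mir367) and an X-linked germline cluster. They take in 268 genes, of which 164 were detected and 0 are in more than 1 list, and hold 83.6% and 84.4% of the counts. Mir92-1, Mir92-2 and Mir18 carry symbols that the stems of the Mir17 list did not match and stayed outside it. Neural lists were set against other-tissue lists (erythroid, leukocyte, striated muscle, liver, epithelial, endocrine and gut, endothelial, mesenchyme) as a log2 ratio of summed CPM. List medians of log2(CPM + 1) were placed among 10000 random lists of the same size from all annotated miRNA genes, and list medians of the ratio between the libraries among 10000 random lists of detected genes matched in 5 bins of level. Random lists drew genes singly, although members of a list can lie in the same genomic cluster. The percentiles treat such members as independent and can be too extreme.

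Genes named in the text were chosen by a rule fixed before the data were examined: the 20 with the highest mean CPM, up to 3 of the most abundant detected members of each list, and the 5 highest in each library relative to the other among genes of at least 100 CPM past the binomial test. Genes named outside this rule are said to be chosen after their values were seen, or are members that a count or a test singled out.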

Results

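MicroRNAs (miRNAs), short RNAs that repress messenger RNAs, were counted in neural tube, the embryonic tissue that gives rise to the central nervous system, dissected from mouse embryos at 15.5 days of development. The samples form 1 group of 2 biological replicates, each a pool of embryos of both sexes from the B6NCrl strain. Library 1 came from 78 embryos and held 7925935 reads, of which 4228685 were counted on the sense strand of an annotated miRNA gene. Library 2 came from 62 embryos and held 11738914 reads, of which 6039889 were counted in this way. With a single group, the data answer which miRNA genes the tissue held, at what level among reads assigned to a gene, and by how much the pools differed. Multimapping reads, 29.4% of the reads of library 1 and 29.7% of library 2, were assigned to no gene. Levels and ranks may therefore be too low for genes with near-identical copies. No comparison between conditions can be made. Values are given as mean ± SD over both libraries (n = 2) unless a library is named, and CPM stands for a gene's counts scaled to the library's total of sense-strand miRNA gene counts.

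Mir10a and Mir10b, which lie in the Hox gene clusters that pattern the body axis, were the most abundant miRNA genes. Mir10a took 17.5% ± 0.588 of the counts (n = 2) and Mir10b took 17.4% ± 0.988 (n = 2). Mir99a followed with 11.8% ± 0.479 (n = 2), so that 3 genes held 46.6% ± 2.06 of all counts. The next were Mirlet7g with 3.96% ± 0.368 and Mirlet7i with 3.60% ± 0.0310, members of the let-7 family that restrains proliferation as cells differentiate. Mir100 reached 2.83% ± 0.106, and Mir487b of the imprinted Dlk1-Dio3 region reached 2.71% ± 0.433. Mir335, hosted by the imprinted gene Mest, took 2.23% ± 0.183. Mir126a, an endothelial miRNA, took 2.08% ± 0.166, and Mir30e took 1.55% ± 0.00830.

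These 10 genes together held 64.3% of the counts in library 1 (95% Wilson interval 64.2 to 64.3) and 66.9% in library 2 (66.8 to 66.9). The gap between the libraries exceeded the counting error. The 20 most abundant genes held 76.4% ± 0.996 and the 100 most abundant held 96.8% ± 0.420. Ranks 11 to 20 were taken by Mir99b, Mir130a, Mir149, Mir26b, Mir143, Mir23b, Mir17, Mir181c, Mir369 and Mir30a, from 14434 ± 1242 CPM for Mir99b to 7571 ± 376 CPM for Mir30a. Mir143 stood out among them for its spread, with 17950 CPM in library 1 and 3951 CPM in library 2. At least 10 counts in both libraries were found for 363 of the 1973 miRNA genes in the tables, and 1264 genes had no sense count in either library. A count of 0 allows a level of up to 0.709 CPM in library 1 and 0.497 CPM in library 2. Intervals and these limits cover counting error only.

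On the mm10 genome, Mir10a (ENSMUSG00000065519.1) lies on chromosome 11 at positions 96317165 to 96317274, outside any other annotated gene on its strand. Mir10b lies in an intron of Hoxd4 and of Hoxd3. Mir99a lies on chromosome 16 at 77598936 to 77599000, in an intron of the non-coding gene Mir99ahg. Mirlet7g lies on chromosome 9 at 106178840 to 106178927, in an intron of Wdr82. Mir335 lies on chromosome 6 at 30741299 to 30741396, in an intron of Mest. Mir126a lies on chromosome 2 at 26591357 to 26591429, inside Egfl7 and overlapping an exon of at least 1 annotated transcript of it. Mir487b lies on chromosome 12 at 109727333 to 109727414.

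Grouped by gene lists fixed before the data were examined, the miRNA genes of the Hox clusters (Mir10, Mir196 and Mir615) held 36.1% ± 1.48 of the counts, with 6 of 6 members detected. The Mir125, Mir99 and Mir100 genes held 16.7% ± 0.755 (6 of 6 detected), the let-7 family held 9.40% ± 0.451 (10 of 10), and the imprinted Dlk1-Dio3 region held 7.90% ± 0.570 (45 of 53). Member numbers count analysed genes only. Mirlet7e and Mirlet7f-1 of let-7, and Mir409, Mir376a, Mir380 and Mir299a of the Dlk1-Dio3 region, were not analysed as genes of their own. They are missing from these numbers and shares. The Mir30 family held 2.89% ± 0.0298, the proliferation-linked Mir17 cluster with its paralogs 2.11% ± 0.347, and the Mir181 family 1.77% ± 0.102. The Mir183 cluster, known from sensory cells, held 0.892% ± 0.0575, with Mir182 at 4168 ± 468 CPM. The Sfmbt2 cluster list, defined by symbol stems and not by position, held 0.366% ± 0.00513 with only 9 of 69 members detected. Of the 60 members not detected, 58 share 20 bases with another precursor, so their reads may have been left out as multimapping. The X-linked cluster known from the germline had 0 of 18 members detected, with 3 counts in library 1 and 2 counts in library 2.

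Neural miRNA genes were present at moderate levels. The neuron-enriched list held 1.35% ± 0.0638 of the counts with 16 of 20 members detected, led by Mir137 at 6917 ± 428 CPM, Mir128-1 at 1275 ± 3.71 CPM and Mir138-1 at 959 ± 39.5 CPM. Mir92b, known from neural progenitors, reached 1831 ± 186 CPM, and with the Mir9 genes held 0.221% ± 0.0199. Mir219a-2 and Mir338, known from oligodendrocytes, reached 1814 ± 171 CPM and 298 ± 11.5 CPM, and the glial list held 0.221% ± 0.0164. The 3 copies of Mir124a, a well-known neuronal miRNA, were below 10 counts in at least 1 library (Mir124a-1 had 8 and 17 counts, Mir124a-2 had 8 and 8, Mir124a-3 had 2 and 5), and were chosen for mention after their values were seen. These copies share a stretch of 20 bases with another precursor and reads aligned to several places were left out of the gene counts, so their levels are uncertain. Mir128-1, Mir138-1, Mir219a-2, Mir487b and the Mir9 genes Mir9-2 and Mir9-3 also share such a stretch with another precursor, and Mir9-1 was not analysed here as a gene of its own, so the share of the Mir9 genes is uncertain as well.

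miRNA genes known from other tissues were also counted. Mir126a stood for endothelium at 20838 ± 1658 CPM. The mesenchyme and smooth muscle list held 15007 ± 10484 CPM (6 of 8 detected), the epithelial list 0.304% ± 0.341 (7 of 7), and the endocrine, pancreas and gut list 0.0985% ± 0.0693 (7 of 8). Lower levels were found for the striated muscle list with 0.0358% ± 0.00553 (6 of 10), the leukocyte list with 0.0335% ± 0.0139 (3 of 4; 0.107% with counts from both strands), the pluripotency list with 0.0231% ± 0.00370 (6 of 11), the erythroid list with 0.0193% ± 0.00136 (3 of 3) and the liver gene Mir122 with 0.00611% ± 0.000685. The medians of the epithelial, mesenchyme and neuron-enriched lists lay at percentiles 99.96, 99.96 and 100 of 10000 random lists of the same size. Those of the Sfmbt2 and X-linked cluster lists were 0 CPM. Their percentile of 0 was thereby fixed, since no random list can have a lower median, and it does not rank them below random lists. Most Sfmbt2 members share 20 bases with another precursor, so the level of that cluster is uncertain. The other 17 lists lay at percentile 88.7 or higher, against a background in which most annotated miRNA genes had no count. Against random lists of detected genes, the medians of the detected members lay at percentile 89.9 for the neuron-enriched list, 80.4 for the epithelial list and 78.1 for the mesenchyme list. The epithelial value rests on the mean of libraries that differed 8.46-fold, and so mainly on library 1. Medians lay at percentile 31.2 for the endocrine and gut list, 18.6 for the erythroid list, 6.53 for the pluripotency list and 0.57 for the striated muscle list.

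**Figure D1:**
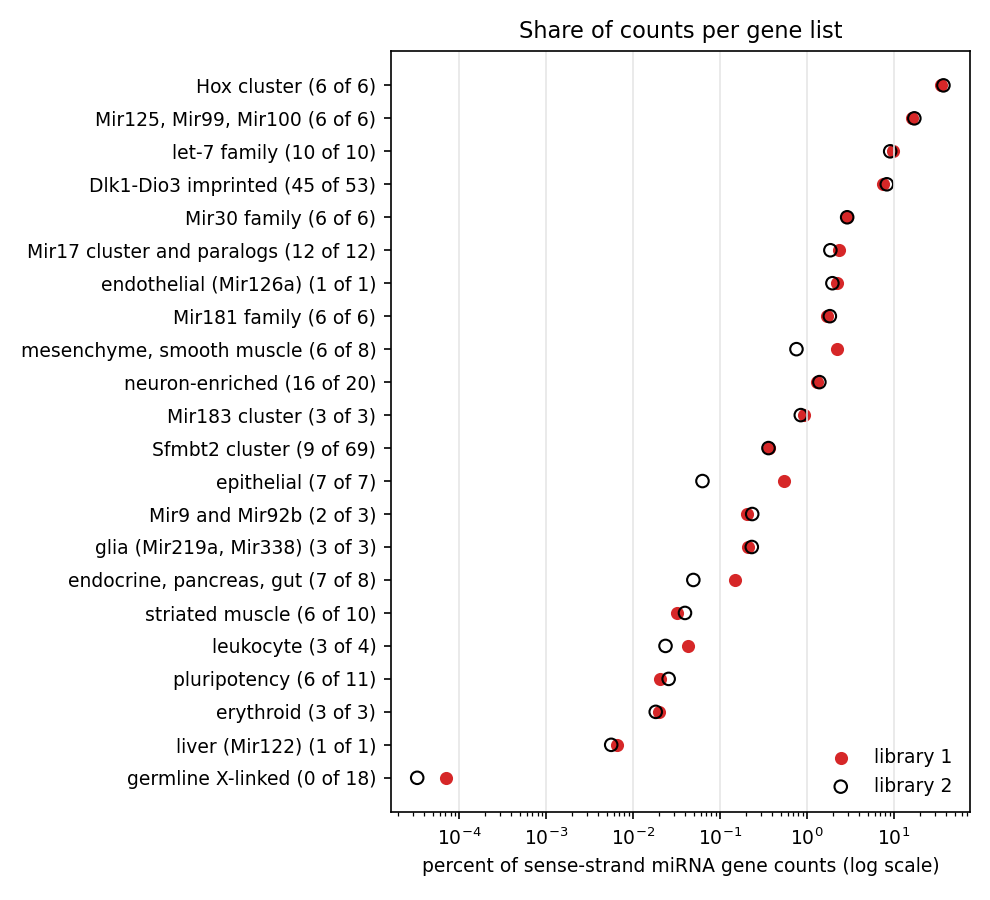
Percent of sense-strand miRNA gene counts held by each gene list (log scale), with 1 point per library and the number of detected members among the analysed ones beside each name. The Hox cluster genes held 35.1% in library 1 and 37.2% in library 2, and the epithelial list lay apart with 0.546% and 0.0631%.

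The neural lists together reached 17907 ± 1001 CPM and the lists of other tissues 40822 ± 16352 CPM. The log2 ratio of neural to other-tissue counts was -1.61 in library 1 and -0.65 in library 2 (mean -1.13 ± 0.67, n = 2). The neural sum differed little between the libraries, with 17199 and 18615 CPM, while the other-tissue sum was 52384 CPM in library 1 and 29259 CPM in library 2. Without the single endothelial gene Mir126a, an alternative added after the data were seen, the ratio was -0.82 in library 1 and 0.96 in library 2 (mean 0.068). The mean was -0.64 without the most abundant member of each side, Mir137 and Mir126a, and -1.79 without members that share 20 bases with another precursor. That last alternative removes such genes and does not restore reads left out as multimapping. Of the neuron-enriched members 13 of 20 share such a stretch, and 2 of 3 in each other neural list. Among other tissues it was 4 of 10 striated muscle, 3 of 8 mesenchyme, 2 of 8 endocrine and gut and 1 of 3 erythroid members. The epithelial, endothelial, leukocyte and liver lists had 0. The ratio may therefore understate the neural side.

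For most miRNA genes the pools gave similar levels. Across the 363 detected genes, Pearson's r of log2(CPM + 1) was 0.976 and Spearman's rho 0.969; genes are not independent replicates. Of the 196 detected genes with at least 100 CPM, 176 lay within 1.5-fold of each other. The counts differed by more than sampling noise, with a chi-square of 116275 on 438 degrees of freedom over the genes with at least 10 counts in both libraries together. An exact binomial test of each gene, two-sided with Benjamini-Hochberg adjustment, found 181 of 363 genes to differ, 93 higher in library 1 and 88 higher in library 2. It compares these libraries, not conditions, and takes account of counting error alone. Differences of at least 2-fold were found for 20 genes higher in library 1 and for 1 gene higher in library 2, Mir5126 with 10 and 33 counts, named after its value was seen.

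**Figure D2:**
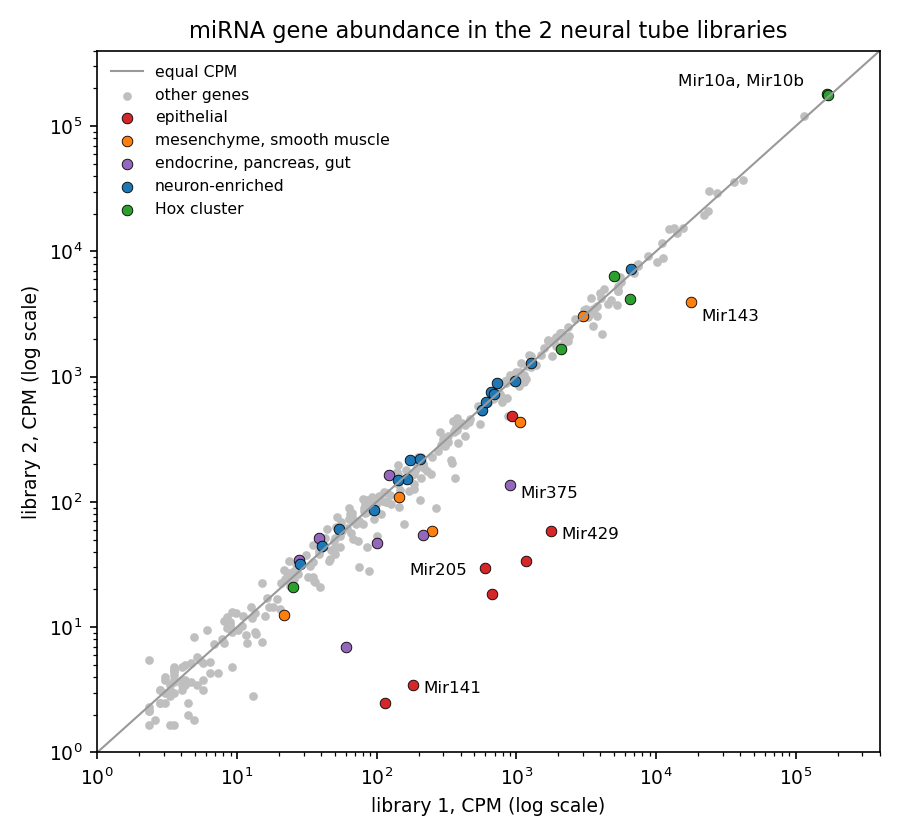
Level of each of the 363 detected miRNA genes in library 1 (x axis) and library 2 (y axis), in CPM on log scales, with 5 gene lists in color and the line of equal CPM. Most genes lie near the line, while Mir429, Mir205, Mir141, Mir375 and Mir143 lie below it, higher in library 1.

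Of the lists with detected members, the epithelial one differed most between the pools. The epithelial list held 0.546% of the counts in library 1 (95% Wilson interval 0.539 to 0.553) and 0.0631% in library 2 (0.0611 to 0.0651), 8.46-fold higher in library 1 (exact counting interval 8.17 to 8.75). All 7 members were higher in library 1, 6 of them at least 2-fold, and 7 were called when adjusted over the list alone; edgeR's exact test, which adds the spread between the pools, called 6, all but Mir203. Among the members of the Mir200 family, which keeps cells epithelial by repressing Zeb1 and Zeb2, Mir200b was 35.3-fold higher (29.2 to 43.0), Mir200c 34.4-fold (29.8 to 39.7) and Mir429 29.8-fold (26.8 to 33.2). Mir429 had 1782 CPM in library 1 and 58.4 CPM in library 2. Mir205, known from stratified epithelium, was 19.7-fold higher (16.9 to 23.0), while Mir203, known from epidermis, was 1.88-fold higher (1.79 to 1.97). The list's median log2 ratio of 5.10 lay at percentile 100 of 10000 random lists matched on level. Random lists drew genes singly, whereas Mir429, Mir200a and Mir200b lie in the same genomic cluster, as do Mir141 and Mir200c. This percentile, and those of other lists with clustered members below, can therefore be too extreme.

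Part of the endocrine, pancreas and gut list moved the same way. Of its 7 detected members, 4 were higher in library 1, 2 were higher in library 2 and 1 did not pass the test; adjusted over the list alone the counts were 4 and 3, and edgeR's exact test called Mir215 and Mir375. Mir375, known from endocrine cells and gut, was 6.45-fold higher in library 1 (5.98 to 6.97) and Mir192, known from gut and kidney, 3.91-fold (3.44 to 4.45). Mir217, known from pancreas, went the other way with a log2 ratio of library 1 to library 2 of -0.46. The list as a sum was 2.91-fold higher in library 1 (2.78 to 3.04), and its log2 ratio of 1.54 was 0.65 without Mir375. Its median lay at percentile 99.97 of the matched random lists.

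Most detected mesenchymal and leukocyte genes were higher in library 1 as well, by the binomial test. By edgeR's exact test, 0 of them were called on the sense strand and 0 genes of the lists that follow. The spread of 34.3% used in that test was estimated from these same libraries, the epithelial genes included, and was 14.8% without 4 tissue lists. A gene not called by it may still differ. In the mesenchyme and smooth muscle list, 5 of 6 detected members were higher in library 1 and 1 in library 2, with the same counts adjusted over the list alone. Mir143, known from smooth muscle, was 4.44-fold higher (4.37 to 4.50) and Mir214, known from mesenchyme, 2.38-fold (2.27 to 2.50), while the cartilage miRNA gene Mir140 had a log2 ratio of -0.05 (exact binomial test, adjusted p = 0.00394). The list was 2.88-fold higher in library 1 (2.85 to 2.92), but its log2 ratio of 1.53 was 0.26 without Mir143. In the leukocyte list, Mir155 was 2.31-fold higher (2.04 to 2.62), Mir223 1.92-fold (1.73 to 2.13), and Mir150 had a log2 ratio of 0.07 (exact binomial test, adjusted p = 0.680). Of its 3 detected members, 2 were higher in library 1, also when adjusted over the list alone, and the list was 1.78-fold higher (1.66 to 1.91). With counts from both strands its log2 ratio was 2.12 in place of 0.84, and edgeR's exact test called Mir142b. The medians of both lists lay at percentiles 99.93 and 98.3 of the matched random lists.

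The Mir17 cluster and its paralogs were also higher in library 1, by factors that differed between members. Of 12 detected members, 8 were higher in library 1 and 4 did not pass the test, also when adjusted over the list alone. Mir17 was 1.21-fold higher (1.20 to 1.23), Mir106b 1.23-fold (1.20 to 1.25) and Mir93 1.13-fold (1.11 to 1.15), and the list as a sum 1.23-fold (1.22 to 1.24). The less abundant X-linked members Mir20b and Mir106a were 2.87-fold and 2.31-fold higher, the 2 members past 2-fold, named after their values were seen. The list's median log2 ratio of 0.44 lay at percentile 99.96 of the matched random lists.

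Some neural genes were slightly higher in library 2. In the neuron-enriched list, 6 of 16 detected members were higher in library 2, 10 did not pass the test and 0 were higher in library 1; 5 were called when adjusted over the list alone. Mir137 had a log2 ratio of library 1 to library 2 of -0.16, and Mir128-1 of -0.04 (exact binomial test, adjusted p = 0.205). The list was 1.09-fold higher in library 2 (1.08 to 1.11), and its median log2 ratio of -0.12 lay at percentile 1.61 of the matched random lists. Mir92b had a log2 ratio of -0.24. It was the 1 called gene of the 2 detected among the 3 members of its list, against 2 adjusted over the list alone. Mir219a-2 had a log2 ratio of -0.23 and was the 1 called gene of the 3 glial members, also when adjusted over the list alone. The 5 genes highest in library 2 relative to library 1, among those of at least 100 CPM, had small differences: Mir1298, hosted by the serotonin receptor gene Htr2c, had a log2 ratio of -0.50, Mir217 of -0.46, Mir615 of -0.39, Mir206 of -0.38 and Mir204 of -0.37.

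The remaining lists differed by less than 1.5-fold as sums, with the X-linked germline cluster not tested. All 6 Mir125, Mir99 and Mir100 genes were higher in library 2, with a list log2 ratio of -0.13, and so were 4 of 6 Mir181 genes, with -0.15. In the Dlk1-Dio3 region 19 of 45 genes were higher in library 2 and 5 in library 1, with a list log2 ratio of -0.18 and Mir487b at -0.36. For these 3 lists the counts adjusted over the list alone were the same. Their median ratios lay at percentiles 3.62, 14.95 and 1.35 of the matched random lists. The Hox cluster genes went both ways, 2 higher in library 1 and 3 in library 2, with Mir615 at -0.39 and a list log2 ratio of -0.12. let-7 genes also went both ways, 2 higher in library 1 and 3 in library 2, with a list log2 ratio of 0.06. Among the Mir30 genes 1 was higher in library 1 and 3 in library 2, and the list log2 ratio was -0.05. These 3 lists gave the same counts adjusted over the list alone. Mir182 was the 1 called gene of the Mir183 cluster, with a log2 ratio of 0.20, and 2 genes were called when adjusted over the list alone.

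Among genes of other tissues, Mir126a had a log2 ratio of 0.13 and Mir122 of 0.20, the latter not past the test (exact binomial test, adjusted p = 0.161). Mir144 was the 1 called gene of the 3 erythroid members, with a log2 ratio of 0.58. Mir206 was the 1 called gene of the 6 striated muscle members, with -0.38. Among the 6 detected pluripotency genes 2 were called, both higher in library 2, Mir302a with -0.45 and Mir302b with -0.51, and the list median lay at percentile 0.11 of the matched random lists. These lists kept those counts when adjusted over the list alone. In the Sfmbt2 cluster 1 gene was higher in library 1 and 2 in library 2, against 1 and 1 adjusted over the list alone.

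**Figure D3:**
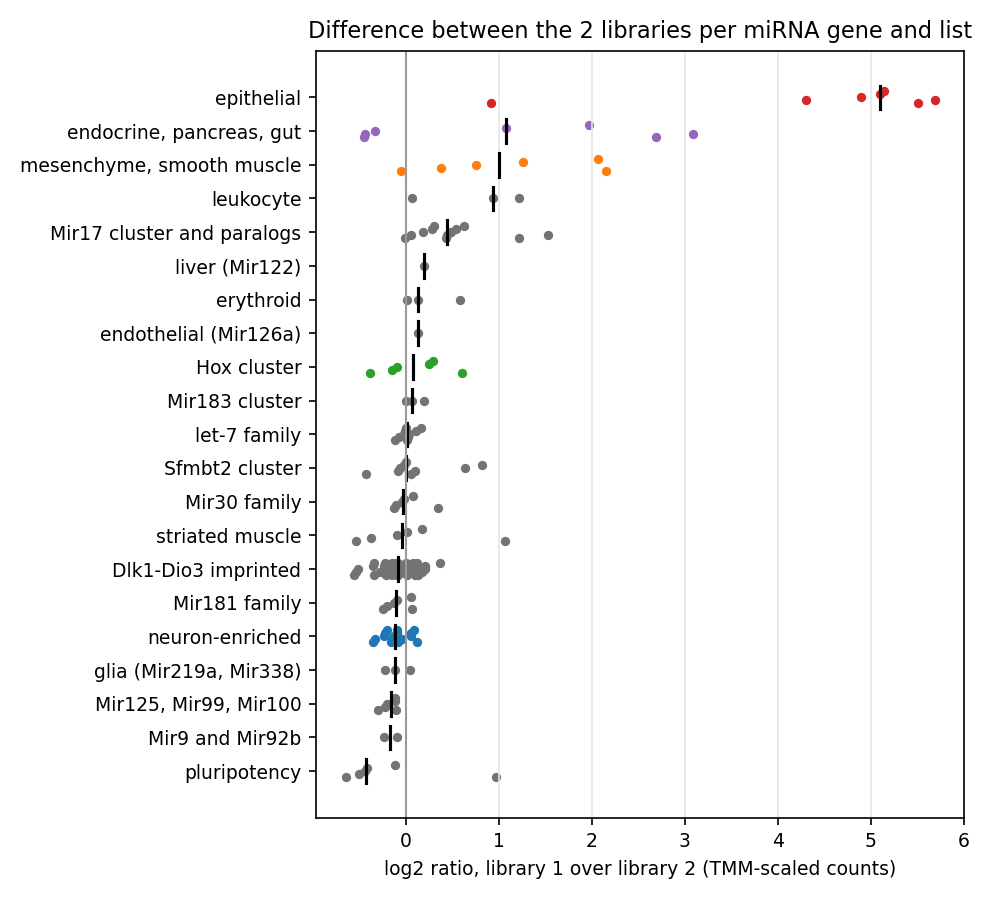
log2 ratio of library 1 to library 2 for each of the 164 detected miRNA genes that belong to a gene list, grouped by list. A bar marks each list's median, and scaling is by TMM factors. The epithelial median is 5.10, and the neuron-enriched median is -0.12.

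The spread between the pools beyond counting error, the biological coefficient of variation from edgeR, was 34.3% over the 363 genes. Without the 23 detected members of the epithelial, endocrine and gut, mesenchyme and leukocyte lists, an alternative added after the data were seen, it was 14.8% over 340 genes. With the spread of 34.3% over all 363 genes put into edgeR's exact test, 8 genes passed in place of 181, namely Mir141, Mir200a, Mir200b, Mir200c, Mir205, Mir215, Mir375 and Mir429, and 8 of 8 were higher in library 1. The spread was estimated from the same libraries it was used to compare.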

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

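The tests in this part were chosen after the counts they explain had been seen, and none of them was planned.

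Counts on the strand opposite to an annotated miRNA gene entered the values above only where both strands are named, and 11 genes had more of them than sense counts, all above the limit of 3 counts. Gm25927, annotated opposite Mirlet7e, had 17881 such counts in library 1 and 24172 in library 2. Gm24321, opposite Mir409, had 14342 and 25463, and Gm25252, opposite Mir376a, had 14010 and 18016. Gm25301, opposite Mir378a, had 10522 and 10124, and Gm24083, opposite Mir191, had 9256 and 11183. Gm25750, opposite Mir380, had 2456 and 3506, and Mir299b, opposite Mir299a, had 2091 and 2611. Mir497b, opposite Mir497, had 827 and 1248, Gm24111, opposite Mirlet7f-1, had 316 and 397, and Gm25641, opposite Mir9-1, had 99 and 178. Mir142b, opposite the leukocyte miRNA gene Mir142, had 5684 counts in library 1 and 975 in library 2, which is 8.10-fold higher in library 1 (exact counting interval 7.57 to 8.68).

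A candidate explanation is that these reads come from the miRNA gene on the other strand, which was not analysed here as a gene of its own. Of all opposite-strand counts, 99.9% lay in genes that overlap a miRNA gene annotated on the other strand, as this explanation needs. Loss of strand in library preparation would leave opposite-strand counts across abundant genes, but their median share was 0 percent in the 141 genes with at least 1000 sense counts in each library. On this hypothesis Mirlet7e, Mir409, Mir376a, Mir378a and Mir191 would each have over 1000 CPM in both libraries, and Mir142 in library 1 alone. No biological explanation was tested, since the design has 1 group.

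Multimapping reads, assigned to no gene, made up 29.4% of the reads of library 1 and 29.7% of library 2. List genes that share 20 bases with another precursor had few counts: their median log2(CPM + 1) differed from that of the other list genes by -6.97 (126 and 142 genes; permutation p = 2e-05, the smallest the permutations can give). A candidate explanation is that reads shared between copies were tallied as multimapping. Without the lists of the Sfmbt2 and X-linked clusters, in which few members were detected, the difference was -1.68 (permutation p = 0.0248). This is short of the 2 units set for the full set. Within lists, with both of these clusters included, the copies were lower in 14 of 17 lists (mean difference -2.84, permutation p = 0.0001, the smallest possible). Both checks were added once the first value was known. Low abundance of these miRNAs cannot be told apart from it by the mean multimapping share of 29.5%, because that tally does not say which genes the reads match.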

How the results depend on the processing

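The alternatives that leave out gene lists or the endothelial gene, those for the list ratios between libraries and detection in single libraries were chosen after seeing the data; the others were planned. Detected genes numbered 573 with at least 1 count in place of 363 with at least 10, by construction of the filter. edgeR's exact test, which adds the spread between pools, called 8 genes in place of 181, since its dispersion exceeds counting error. The coefficient of variation was 14.8% without 4 tissue lists in place of 34.3%. These lists hold the 8 genes called by edgeR's exact test, but also genes that differed little, such as Mir140 (log2 ratio -0.05). The mean neural to other-tissue log2 ratio turned from -1.13 to 0.068 without Mir126a, which holds much of the other-tissue counts. The log2 ratio between libraries was 0.65 in place of 1.54 for the endocrine and gut list without Mir375, 0.26 in place of 1.53 for the mesenchyme list without Mir143, and 2.12 in place of 0.84 for the leukocyte list with both strands, which adds the counts of Mir142b. The other 41 alternatives for main results, those without 1 library included, stayed within their limits; the neural ratio was -1.79 without near-identical copies. The split of differing genes was 93 to 88 with TMM, 94 to 82 with DESeq2 size factors, 103 to 68 with library sizes alone, 88 to 92 without a filter and 98 to 90 with both strands. With both strands 19 list shares and 59 named genes stayed within 1 SD, while 3 and 8 moved further. This SD is that of the 2 libraries, so a move past it can reflect libraries that lay close together. Mir30e moved past it, from 15470 to 15207 CPM, whereas Mir10a did not, from 174760 to 171792 CPM. TMM sizes moved 0 of 67 named genes, but the factors of 1.012 and 0.988 act in opposite directions and can cancel in a mean. Without the 10 most abundant genes, which changes the denominator, 21 list shares moved, and the endothelial list had no member left. Leaving out either library gave 375 to 389 detected genes, a share of the 10 most abundant genes of 64.3% to 66.9% and a neural ratio of -1.61 to -0.65; with 2 libraries each value lies within 1 SD of the mean by arithmetic, so this says nothing about stability. No paired analysis was possible because there is 1 group. Depth limits genes near 10 counts, and 352 genes were detected when library 2 was thinned to the depth of library 1.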

Other observations

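The tests in this part were chosen after the ratios between the libraries had been seen, except that of a further epithelial list, whose members and bound were written before their ratios were looked at.

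Several genomic clusters of miRNA genes had median ratios above 0 between the pools; those given here were chosen after their values were seen, and most members of the first pair belong to the Mir17 list of the report. In the X-linked cluster from Mir363 to Mir106a, on chromosome X at 52741693 to 52742567, the 6 detected genes had log2 ratios of library 1 to library 2 from 0.44 to 1.63, with a median of 0.92. The related cluster from Mir17 to Mir92-1, on chromosome 14, had a median of 0.36 over 6 genes. Outside the gene lists, the cluster of Mir23a, Mir27a and Mir24-2 on chromosome 8 had a median of 0.47 over 3 genes, and Mir221 with Mir222 on chromosome X a median of 0.33. Mir224 with Mir452, also outside the lists, had a median of 0.63, with ratios of 0.01 and 1.25. Other clusters had medians below 0, such as Mir302b to Mir302d at -0.47 and Mir216a with Mir217 at -0.40.

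Epithelial miRNA genes were 8.46-fold higher as a list in library 1; counting error does not account for this, as the lower bound of the log2 ratio was 3.03. A lower share of neural tissue would raise other cell types alike, but the median of the 10 detected erythroid, striated muscle and endothelial genes was 0.08, 5.02 below the epithelial one; these lists were picked with the ratios known, and over all 27 detected genes of the other tissue lists, it was 0.20, 4.90 below, although the mesenchyme list (2.88-fold) and the leukocyte list (1.78-fold; log2 ratio 2.12 with both strands, where the counts opposite Mir142b, not among the 27, were 8.10-fold higher) were higher too. Epithelium of another organ in the first pool is a candidate explanation that stays open. In the endocrine and gut list, Mir215 (8.50-fold), Mir375 (6.45-fold), Mir192 (3.91-fold) and Mir194-2 (log2 ratio 1.07) were also higher in library 1. Mir194-1, with 48 counts in library 1 and 9 in library 2, missed the count minimum. Mir216b (log2 ratio -0.44) and Mir217 (-0.46) of that list were higher in library 2, and the list's ratio of 1.54 was 0.65 without Mir375. A further epithelial list was expected to have a median above 1 if epithelium of another organ had entered the first pool. A median below 0.5 was set in advance to count against this. The median found was 0.16. This lies below the bound of 0.5 set in advance, but by less than the SD of 0.504 of the 4 detected members (Mir31 at 0.92, Mir34c at 0.35, Mir449a at -0.03 and Mir34b at -0.23), a condition on the margin applied after the median had been seen; Mir802, with 19 counts in library 1 and 3 in library 2, missed the count minimum in library 2, and with it the median was 0.35 (SD 1.29). A difference in dissection or in the embryos of the pools was not tested, and the design has no group that would separate it from the library.

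A hypothesis was that neighbouring miRNA genes, often made from 1 transcript, differ together between the pools. In 44 clusters of detected genes within 10 kb on the same strand (151 genes), the median over clusters of the absolute difference between members' log2 ratios was 0.212, against a median of 0.336 when the ratios were reassigned at random among all detected genes, and 99.9% of 2000 reassignments gave a larger value. Reassigned among the 151 clustered genes alone, a test added later, the median was 0.361 and 99.95% of 2000 gave a larger value. This is consistent with shared transcription of neighbours. Neighbouring paralogs that resemble each other could give the same pattern through shared regulation or shared reads, which was not tested.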
